A study of Mus musculus with 10 samples.

How the data were processed

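RNA sequencing of whole placenta at gestational day 12.5 was available for 6 AVP-infused and 4 saline-infused C57BL/6J mouse samples. Per the labels' protocols, RNA was isolated with the mirVana kit and made into libraries with the Illumina TruSeq stranded mRNA kit, which selects polyadenylated RNA. Per the submitters' processing notes, the tool was kallisto 0.43.1 and the genome build mm10. The authors deposited 1 table of TPM values, which kallisto scales to transcript length and to a fixed total per library. The transcript annotation and the way in which transcripts were chosen are not given in the sources used here.

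The deposited TPM table has 31537 rows and 10 value columns, and each row carries 1 gene name and 1 transcript identifier. Each gene name stands for a single transcript, so a gene whose main isoform was not chosen can appear low. The TPM of the rows summed to 86.5% to 87.2% of that total per library, and the remaining TPM belongs to transcripts not analysed here. There were 26 names that read as dates, which spreadsheet programs make from gene names, and these were not named in the text. The names are in capitals. For 22697 of them a mouse symbol in GENCODE or RefSeq gave the usual spelling. Coordinates and transcript lengths came from GENCODE on GRCm38, the assembly that mm10 also denotes. No row is named as a mitochondrially encoded gene, so the planned mitochondrial share was not computed. TPM keeps no depth, and the number of reads per library is unknown.

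Columns were assigned to AVP or saline by their names, which do not carry the replicate numbers of the labels, so samples could not be paired. No pair of libraries looked like a library deposited again. The lowest median absolute log2 difference of any pair was 0.128, and at most 2 values above 0 were identical in any pair (3 of the 45 pairs held any).

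Genes with TPM of at least 1 in at least 4 libraries were tested (13293 genes). TPM values were taken as log2(TPM + 1) without further scaling and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided). The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 on the adjusted p. The fit held no covariate. Confidence intervals are at 95%. Before the data were examined, 43 gene lists with 682 different genes were fixed, and 616 of these genes had a row. The 40 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance one way without comparing them with other genes, were alternatives. Adult globins (2 members tested), T helper and inflammatory cytokines (1) and mitochondrially encoded genes (0) were too few to test.

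The rule for naming genes was also fixed before the data were examined. It took up to 12 genes per direction with the largest change among those past the threshold, with mean TPM of at least 5 in the higher group and no predicted-gene name or pseudogene. Where fewer passed, the direction was filled up to 6 genes by the smallest unadjusted p. It further named 15 genes of the vasopressin system, angiogenic factors and placental hormones whatever their values, and 2 to 4 members with the smallest unadjusted p of each list described by examples. The lists described by examples, 28 of them, were chosen after the values were seen, and the other lists are given by counts. The single library values of Gzmd, Cryab, Prl8a2, Hbb-y, Eif2s3y and Xist were also chosen after the values were seen.

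Library makeup was compared with exact permutation tests over all 210 splits of the 10 libraries into 6 and 4 (scipy 1.17.1, two-sided), where the smallest possible p is 0.00952. Named genes and makeup values were screened for a library far from the others of its group with Dixon's ratio at its 95% critical value.

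The gene and list tests were tested on simulated data for the AVP and saline comparison, with 13293 genes drawn from the real means and spreads and 200 genes changed in each of 20 simulations. Of genes changed 1.5-fold on the scale tested, 38.6% were recovered, against 70.7% of those changed 2-fold and 91.4% of those changed 4-fold, and 5.01% of the calls were false. A list shifted by 0.5 on the log2 scale was called in 20 of the 20 simulations. Genes were simulated as independent, which the real lists are not.

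Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalization, rescaling without haemoglobin and the 20 most abundant other genes, no variance trend, robust variance, library weights, the Y-linked mean as a covariate, a threshold of 0.10 and leaving out each library. Alternatives added after seeing the data were the number series (04 or 97) as a covariate, each series alone, libraries of a group that share a number averaged or taken as a random block, the yolk sac marker mean as a covariate, leaving out the 5 libraries with Afp of at least 1000 TPM, leaving out small RNAs and accession-named rows, and an estimated correlation together with the series covariate or without those 5 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.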

Results

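Whole placentas of pregnant C57BL/6J mice, an inbred laboratory strain, were profiled by RNA sequencing on gestational day 12.5. The dams had received arginine vasopressin (AVP), the antidiuretic hormone, at 24 ng per hour or saline from osmotic pumps under the skin, starting 3 days before mating. The series set out to ask whether AVP infusion models preeclampsia, the hypertensive disorder of pregnancy, and the comparison here is of the placental transcriptome between the groups. There were 6 AVP libraries and 4 saline libraries. Each library was given as TPM, an abundance scaled to transcript length and to the library total, for 31537 transcripts, and TPM keeps no record of sequencing depth, so the depth behind each value is unknown. Libraries are named below by their deposited column names (AVP_042_4, Sal_043_5 and so on), which show the group. The number after the group was shared by 3 AVP libraries (974) and by 2 saline libraries (975), and 043 occurred in both groups. The labels do not say whether a shared number marks a dam or a litter, so the p-values measure the spread between these samples and may be too small.

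Yolk sac genes were abundant in some libraries of both groups and nearly missing from others. Afp, the alpha-fetoprotein gene of visceral endoderm, was listed at 6382 to 8339 TPM in AVP_042_4, AVP_043_4, AVP_974_2 and AVP_976_4, at 203 TPM in AVP_974_4 and at 18.5 TPM in AVP_974_5. Among the saline libraries it was listed at 5966 TPM in Sal_975_5 and at 8.53 to 38.1 TPM in the other 3. Apoa1, an apolipoprotein gene, and Ttr, the transthyretin gene, followed the same libraries. Apoa1 was at 1783 TPM in Sal_975_5 and at 2.70 to 11.5 TPM in the other saline libraries, and Ttr was at 717 TPM against 3.18 to 6.77 TPM.

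Genes of the maternal decidua and of uterine natural killer cells also varied widely within each group. Gzmd, a granzyme gene of these killer cells, ranged from 123 to 3105 TPM in AVP and from 50.2 to 1848 TPM in saline. Cryab, a small heat shock gene of the decidua, ranged from 24.8 to 1198 TPM in AVP and from 65.9 to 806 TPM in saline. Prl8a2, a prolactin family hormone of the decidua, was lowest in AVP_974_2 at 189 TPM and highest in AVP_042_4 at 3848 TPM. The embryonic globin Hbb-y varied less, at 9873 ± 1941 TPM in AVP (SD, n = 6) and 9637 ± 1712 TPM in saline (SD, n = 4).

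Y-linked and X-inactivation transcripts separated the libraries within each group. Eif2s3y, a Y-linked translation factor gene, was at 19.8 and 20.2 TPM in AVP_974_2 and AVP_976_4, and at 20.2 and 25.9 TPM in Sal_046_5 and Sal_975_2. It was at most 0.0446 TPM in the other AVP libraries and in Sal_043_5. In Sal_975_5 it was at 6.49 TPM, and Xist, the RNA of the inactive X chromosome, was at 24.2 TPM in the same library. None of the 4 measures of library makeup differed between the groups after Benjamini-Hochberg adjustment over the 4 exact permutation tests (two-sided). A mean of 12894 ± 203 genes reached 1 TPM in AVP and 12724 ± 94.3 in saline (SD, n = 6 and 4, exact permutation p = 0.133, adjusted p = 0.483). The haemoglobin genes took 2.71% ± 0.555 of the TPM in AVP and 2.75% ± 0.616 in saline (SD, n = 6 and 4, exact permutation p = 0.933, adjusted p = 0.933). The share in the 20 most abundant genes was 18.7% ± 1.81 and 19.9% ± 1.85 (exact permutation p = 0.362, adjusted p = 0.483), and the summed TPM of Y-linked genes was 11.8 ± 17.5 and 20.9 ± 18.3 (exact permutation p = 0.286, adjusted p = 0.483).

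**Figure D1:**
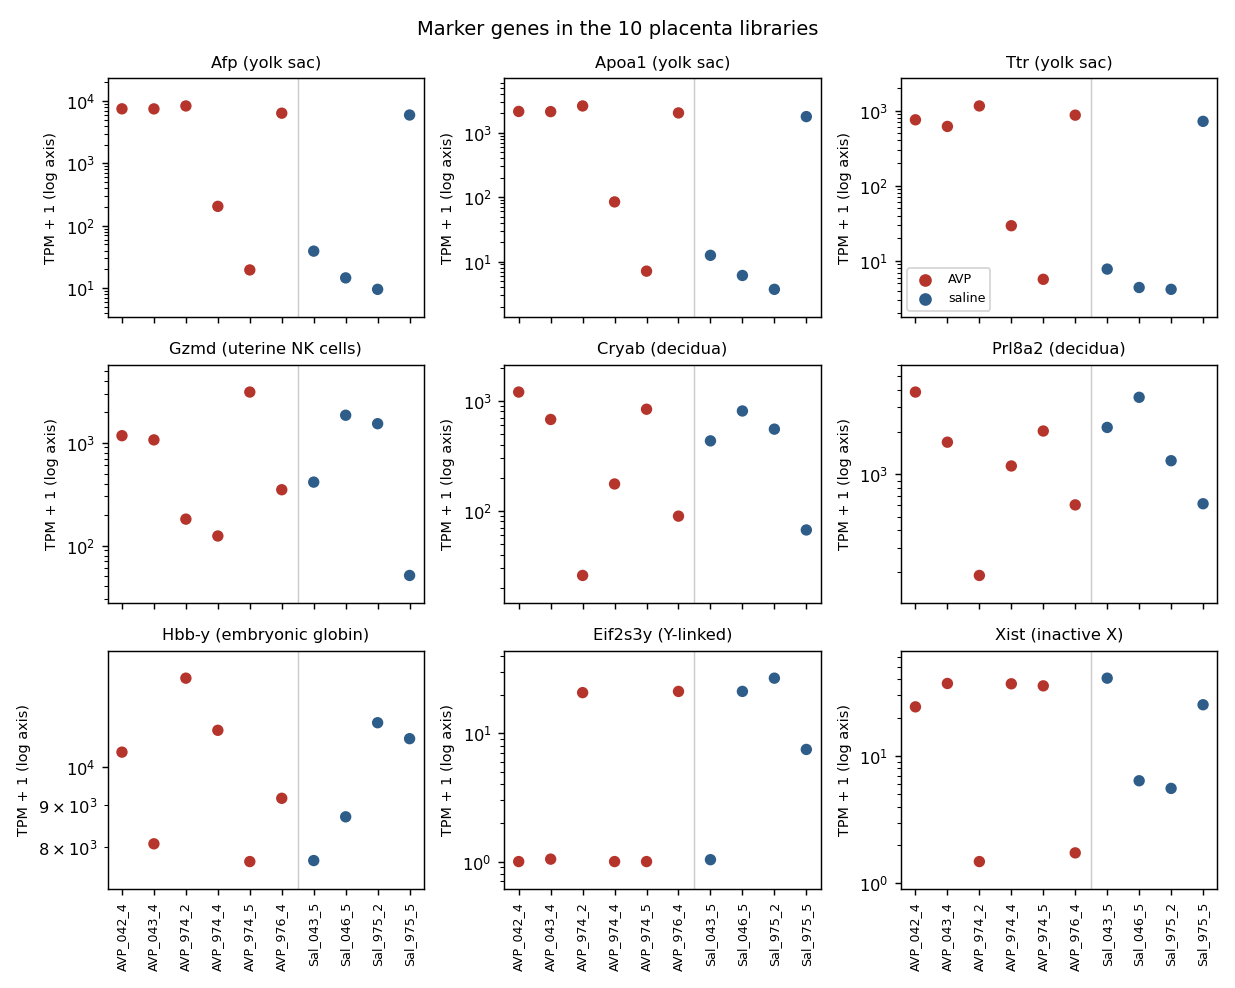
Marker genes in each of the 10 libraries, as TPM + 1 on log axes, with the library on the horizontal axis, AVP libraries in red and saline libraries in blue. Afp, Apoa1 and Ttr are high in 4 AVP libraries and in Sal_975_5, where Afp is at 5966 TPM.

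AVP and saline libraries were intermixed on the leading principal components. Component 1 of the expression values held 34.5% of the variance and component 2 held 22.1%. On component 1, Sal_975_5 lay with AVP_974_2 and AVP_976_4, and on component 2 the 2 AVP libraries with numbers beginning 04 stood apart. Sal_975_5, AVP_974_2 and AVP_976_4 scored 29.8 to 46.2 on component 1. They had high Afp, and also low Cryab (24.8 to 88.3 TPM) and Gzmd (50.2 to 347.8 TPM). AVP_042_4 and AVP_043_4, also with high Afp, scored 8.64 and 12.1. AVP_974_4, with low Gzmd (122.8 TPM), scored 0.389. Which markers the scores follow was not tested. The highest correlation between any pair of libraries was between an AVP and a saline library, AVP_976_4 and Sal_975_5, at Pearson r = 0.979 across genes.

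**Figure D2:**
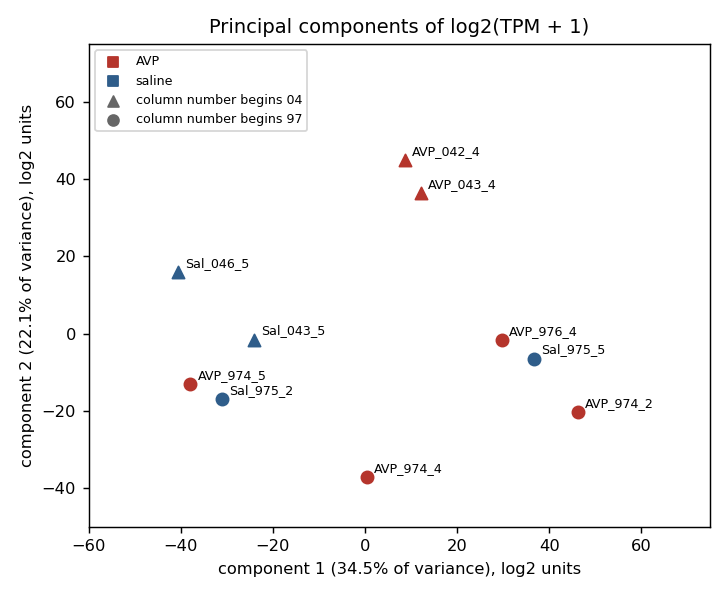
Scores of the 10 libraries on the 2 leading principal components of log2(TPM + 1), in log2 units, with AVP in red, saline in blue, column numbers beginning 04 as triangles and those beginning 97 as circles. AVP and saline libraries are intermixed on component 1, which holds 34.5% of the variance.

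Between AVP and saline placentas, 1 of the 13293 genes tested passed the threshold, the microRNA gene Mir669h. It was listed at 0 in all 6 AVP libraries and at 6.57, 3.48, 3.83 and 6.83 TPM in Sal_043_5, Sal_046_5, Sal_975_2 and Sal_975_5 (limma, adjusted p = 0.000397). The AVP values of Mir669h show no spread, so the spread behind this p comes from the saline values and from limma's trend over genes. The smallest possible two-sided exact permutation p for 6 against 4 libraries is 0.00952. No gene passed as higher in AVP. At an unadjusted p under 0.05, limma gave 378 genes higher and 253 lower, 631 in all, where 665 would be expected by chance. This count depended on single libraries: leaving out 1, it ran from 292 (without Sal_046_5) to 1304 (without Sal_975_5). With library weights it was 1413. The lowest adjusted p after Mir669h was 0.832. The ranges of the groups did not overlap for 88 genes, which is 0.662% of those tested, against 0.952% by chance. The median 95% interval of a log2 fold change reached 0.33 to either side.

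Mir669h lies on chromosome 2 from 10518155 to 10518279, on the plus strand, in the mouse assembly GRCm38. It is 125 nucleotides long in the annotation and lies inside Sfmbt2, an imprinted Polycomb-family gene at 10370510 to 10595253 on the same strand. None of the 7 annotated Sfmbt2 transcripts has an exon there, so the position is intronic. Sfmbt2 itself was at 24.2 ± 4.59 TPM in AVP and 30.2 ± 4.36 TPM in saline (SD, n = 6 and 4, limma adjusted p = 0.867). The libraries were made with an mRNA kit, and the number of reads behind these values is unknown. Mir669h was not past the threshold within the 97 libraries alone (4 AVP against 2 saline, adjusted p = 0.124) or within the 04 libraries alone (2 against 2, adjusted p = 0.0582). These sets hold fewer libraries, and in each of them the AVP libraries were at 0 and the saline libraries at 3.48 TPM or more. A filter of 5 TPM in 4 libraries removed it, leaving 0 genes past the threshold and 447 at an unadjusted p under 0.05.

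The genes with the next smallest p in each direction did not pass. Among those lower on average in AVP, Gramd2 was at 18.6 ± 1.97 TPM in AVP and 28.5 ± 3.24 TPM in saline (SD, n = 6 and 4, limma adjusted p = 0.832). Sema3f, a semaphorin gene, was at 56.1 ± 4.80 and 73.8 ± 6.00 TPM, Dna2, a nuclease and helicase of DNA replication, at 19.3 ± 2.50 and 27.5 ± 3.38 TPM, and Rapgef3, the cyclic AMP-activated exchange factor Epac1, at 11.4 ± 1.44 and 16.8 ± 2.62 TPM. A transcript named in the table only by a sequence accession was listed at 0 in 5 AVP libraries, at 2.11 TPM in AVP_043_4 and at 2.31 to 15.8 TPM in saline. Among those higher on average in AVP, Dgcr6 was at 17.2 ± 1.71 TPM in AVP and 12.8 ± 0.819 TPM in saline. Slc22a18, an imprinted membrane transporter gene, was at 78.1 ± 15.6 and 51.8 ± 6.92 TPM, and the small nucleolar RNA Snord104 at 220.3 ± 53.4 and 129.9 ± 26.5 TPM. Vps13c, a lipid transfer protein gene, was at 7.69 ± 0.979 and 5.32 ± 0.612 TPM, Tmem63a, an ion channel gene, at 5.65 ± 2.60 and 1.29 ± 1.38 TPM, and Retn, the resistin gene, at 5.55 ± 1.83 and 2.77 ± 0.764 TPM. The adjusted p was 0.867 for each of these genes apart from Gramd2.

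**Figure D3:**
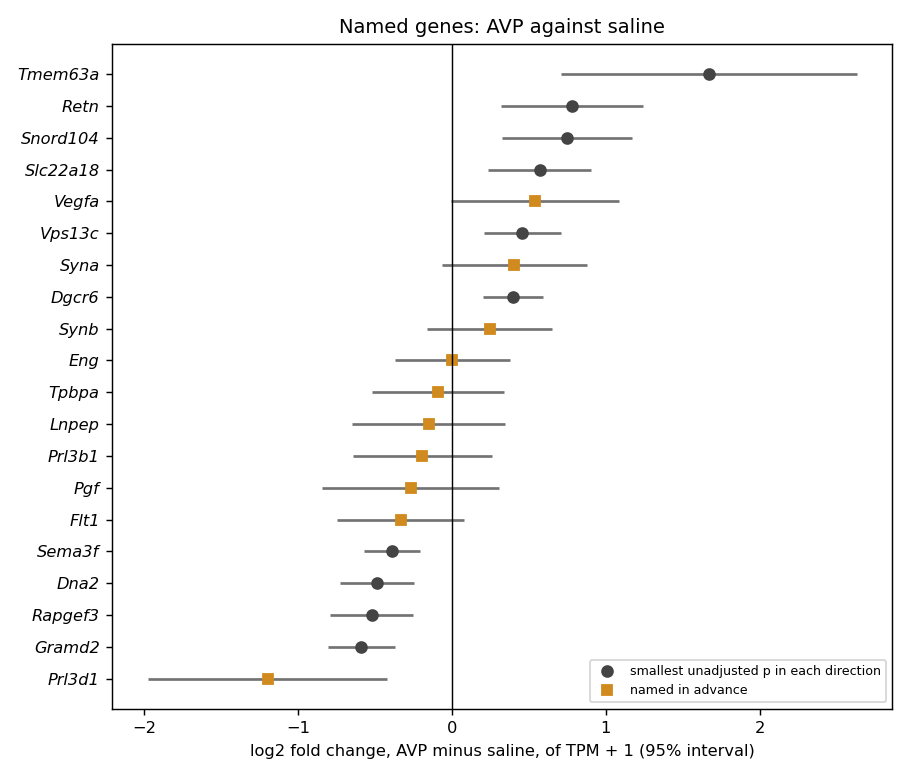
Log2 fold change of TPM + 1, AVP minus saline, with its 95% interval from limma, for the genes with the smallest unadjusted p in each direction (dark circles) and the genes named in advance (orange squares). None of the genes drawn passed the threshold, and Mir669h and the accession-named transcript are left out because 5 or more AVP libraries list them at 0.

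The vasopressin receptors were hardly detected in any placenta. Avpr1a was at 0 to 0.0582 TPM across the AVP libraries and 0 to 0.0481 TPM across saline, Avpr1b at 0.0145 to 0.0946 and 0 to 0.0634 TPM, and Avpr2, the renal-type receptor, at 0 to 0.107 and 0 to 0.0613 TPM. The oxytocin receptor gene Oxtr was at 0.0131 to 0.19996 TPM in AVP and 0.0128 to 0.0634 TPM in saline. These receptors were below the filter and were not tested. Lnpep, which encodes the aminopeptidase that degrades vasopressin and oxytocin, was at 5.79 ± 2.00 TPM in AVP and 6.41 ± 1.46 TPM in saline (SD, n = 6 and 4, limma adjusted p = 0.975). Gnaq, the G protein subunit downstream of the vasopressor receptor, was at 14.4 ± 0.872 and 15.9 ± 2.29 TPM. Of the 5 measured members of the vasopressin and oxytocin list, 3 averaged higher and 2 lower (camera adjusted p = 0.615), and after quantile normalization or rescaling without the most abundant genes 2 averaged higher and 3 lower. Ren1, the renin gene, was not analysed here.

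None of the angiogenic factors measured in preeclampsia passed the test. Flt1, the VEGF receptor gene that also gives the soluble inhibitor sFlt1, was at 337.9 ± 83.5 TPM in AVP and 418.6 ± 64.2 TPM in saline (SD, n = 6 and 4, log2 fold change -0.33, 95% interval -0.75 to 0.08, limma adjusted p = 0.867). The table gives 1 transcript per gene, so soluble and membrane forms are not separated. Pgf, placental growth factor, was at 25.6 ± 8.996 and 30.6 ± 8.65 TPM, and its interval ran from -0.84 to 0.31. Vegfa was at 14.5 ± 1.88 TPM in AVP and 10.4 ± 4.70 TPM in saline, with an interval from -0.01 to 1.08. Eng, the endoglin gene, was at 18.6 ± 3.96 and 18.3 ± 2.30 TPM, with an interval from -0.37 to 0.37. Nrp1, a VEGF co-receptor gene, was at 6.80 ± 1.54 and 5.14 ± 1.18 TPM. Of the 12 measured genes of this list 8 averaged higher in AVP and 4 lower, and 6 higher and 6 lower after quantile normalization (camera adjusted p = 0.476). Of 14 endothelial genes 10 averaged higher (8 after quantile normalization, adjusted p = 0.476), with Sox18, an endothelial transcription factor gene, at 12.3 ± 2.19 and 10.1 ± 2.37 TPM and Cdh5, the VE-cadherin gene, at 271.9 ± 37.5 and 318.1 ± 52.5 TPM.

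**Figure D4:**
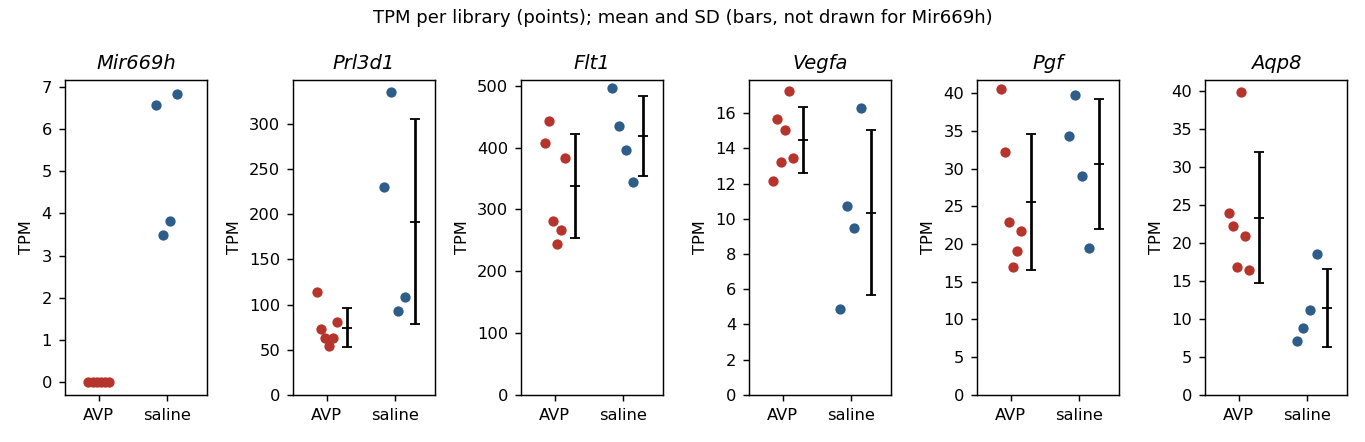
TPM of 6 genes in each library, AVP in red and saline in blue, with the mean and SD of each group as black bars except for Mir669h, whose AVP libraries are all listed at 0. Flt1, Pgf and Vegfa overlap between the groups, and the AVP libraries of Prl3d1 lie between 53.8 and 114.1 TPM against 93.2 to 334.6 TPM in saline.

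None of the hormones of trophoblast giant cells and the junctional zone passed the test. Prl3d1, placental lactogen I, was at 74.4 ± 21.5 TPM in AVP and 191.4 ± 113.3 TPM in saline (SD, n = 6 and 4, log2 fold change -1.20, 95% interval -1.98 to -0.42, limma adjusted p = 0.867). It shares most of its sequence with Prl3d2 and Prl3d3, so the split between these genes is uncertain. Prl3b1, placental lactogen II, was at 15807 ± 3194 and 18010 ± 3648 TPM, and Tpbpa, the spongiotrophoblast marker, at 19786 ± 3000 and 21250 ± 4868 TPM, with the sign of its difference turned after quantile normalization. Of 22 prolactin family genes 14 averaged lower (camera adjusted p = 0.0608, and 0.141 with the number series as a covariate). Prl7d1 was at 1843 ± 308.3 and 2453 ± 406.6 TPM, Prl6a1 at 125.9 ± 56.1 and 194.6 ± 41.9 TPM, and Prl3a1 at 2.91 ± 2.54 and 0.681 ± 0.565 TPM. Of 14 giant cell genes 10 averaged lower (adjusted p = 0.0871), with Prl2c3, a proliferin gene, at 2493 ± 1237 and 4847 ± 3034 TPM and Stra6, the retinol-binding protein receptor gene, at 90.2 ± 18.0 and 69.5 ± 15.8 TPM. Of 21 junctional zone genes, which share most members with the prolactin family, 12 averaged lower (11 after quantile normalization, adjusted p = 0.214), and of 22 pregnancy-specific glycoprotein genes 13 did (adjusted p = 0.174). Within that family Ceacam9 was at 140.1 ± 60.8 and 242.6 ± 76.3 TPM and Ceacam3 at 245.7 ± 76.0 and 347.8 ± 67.4 TPM. Members of these families are near copies of each other, so single-gene values are uncertain.

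Of the 40 gene lists tested, 5 passed camera with a preset inter-gene correlation of 0.01, and none of the 5 passed with an estimated correlation. Over all genes tested none of their members passed. The yolk sac and visceral endoderm list had all 12 measured members higher on average in AVP, with a median log2 fold change of 2.62 (camera adjusted p = 0.000107, adjusted p = 0.838 with an estimated correlation). Afp was at 18.5 to 8339 TPM in AVP and 8.53 to 5966 TPM in saline, Apoa1 at 6.10 to 2611 and 2.70 to 1783 TPM, Apoc2 at 0.880 to 200.4 and 0 to 115.5 TPM, and Ttr at 4.68 to 1150 and 3.18 to 717 TPM. The values followed the libraries with high Afp in both groups. The list was not past the threshold within the 97 libraries alone (camera adjusted p = 0.516) and was within the 04 libraries alone (adjusted p = 7.1e-18), where both AVP libraries and neither saline library had high Afp. Without the 5 libraries with Afp of at least 1000 TPM it was 0.0274 (adjusted p = 0.6248 with an estimated correlation).

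The labyrinth trophoblast list had all 16 measured members higher on average in AVP (15 after median-ratio scaling or rescaling), with a median log2 fold change of 0.23 (camera adjusted p = 0.000442, adjusted p = 0.838 with an estimated correlation). The labyrinth is the exchange zone of the mouse placenta. Syna and Synb, the syncytin genes of its syncytiotrophoblast, were at 95.3 ± 25.6 and 65.7 ± 13.5 TPM in AVP and at 72.3 ± 20.4 and 55.6 ± 13.4 TPM in saline (SD, n = 6 and 4, limma adjusted p = 0.867 and 0.891). Cebpa was at 27.1 ± 2.68 and 20.8 ± 5.90 TPM, and Hsd11b2, which inactivates maternal glucocorticoid, at 163.3 ± 47.0 and 110.2 ± 34.8 TPM. Gjb2, a gap junction gene, was at 575.2 ± 118.4 and 443.7 ± 110.7 TPM and Slc40a1, the iron exporter ferroportin, at 69.3 ± 13.3 and 54.0 ± 13.8 TPM. Syna, Gjb2 and Hsd11b2 were highest in AVP_974_4, at 147.4, 813.6 and 243.5 TPM, and without that library the camera adjusted p of the list was 0.00378. Within the 97 libraries alone the adjusted p of the list was 0.120 and within the 04 libraries alone 0.00184. It was 0.0365 with the yolk sac marker mean as a covariate and 0.00334 without the 5 libraries with high Afp. Sal_975_5, with high Afp, was the highest saline library for Cebpa (28.85 TPM), Hsd11b2 (154.2 TPM) and Gjb2 (564.6 TPM). It was also highest for Slc40a1 (72.99 TPM) and Synb (72.26 TPM), but Sal_043_5 was for Syna. In AVP_974_4 Afp was at 203 TPM. How much of the difference goes with tissue share was not decided by these fits.

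The unfolded protein and integrated stress response list had 17 of 21 measured members lower on average in AVP, with a median log2 fold change of -0.14 (camera adjusted p = 0.0143, adjusted p = 0.838 with an estimated correlation). Hyou1, an endoplasmic reticulum chaperone gene, was at 105.6 ± 39.9 TPM in AVP and 160.1 ± 37.8 TPM in saline (SD, n = 6 and 4, limma adjusted p = 0.867). Hsp90b1, another chaperone gene, was at 1111 ± 179.1 and 1272 ± 148.3 TPM, Asns, asparagine synthetase, at 44.0 ± 7.18 and 53.3 ± 10.55 TPM, and the stress-induced transcription factor gene Atf3 at 37.8 ± 8.42 and 30.4 ± 3.11 TPM. The adjusted p was 0.139 without AVP_974_2, 0.0868 without AVP_974_4, 0.110 without Sal_043_5 and 0.0554 without Sal_046_5. It was 0.120 within the 97 libraries, 0.129 within the 04 libraries and 0.104 with the libraries of a group that share a number averaged. It was 0.0782 after quantile normalization and 0.101 with the yolk sac marker mean as a covariate.

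The embryonic and yolk sac type erythroid list had 10 of 11 members lower on average in AVP (median log2 fold change -0.19, camera adjusted p = 0.0486, adjusted p = 0.838 with an estimated correlation). Slc4a1, the anion exchanger of red cells, was at 13.7 ± 6.18 and 17.8 ± 3.85 TPM, the embryonic globin Hbb-bh1 at 494.9 ± 390.0 and 691.0 ± 292.8 TPM, Ermap at 2.85 ± 1.38 and 4.88 ± 1.89 TPM, and Rhag at 1.18 ± 0.790 and 1.69 ± 0.497 TPM. In the renin-angiotensin list 5 of 7 members averaged higher (median log2 fold change 0.38, camera adjusted p = 0.0486, adjusted p = 0.838 with an estimated correlation). Agt, the angiotensinogen gene, was at 28.7 to 50.3 TPM in the 4 AVP libraries with high Afp, at 25.1 TPM in Sal_975_5 and at 1.21 TPM or less in the other 5 libraries. Atp6ap2, the prorenin receptor, was at 41.5 ± 5.16 and 33.1 ± 4.23 TPM, Ace2 at 3.17 ± 1.51 and 1.65 ± 0.820 TPM and Agtr1a, an angiotensin II receptor gene, at 1.37 ± 0.520 and 0.799 ± 0.211 TPM. Within the 97 libraries alone the adjusted p was 0.118 for the erythroid list and 0.707 for the renin-angiotensin list, and within the 04 libraries alone it was 0.0136 and 0.00248. The adjusted p of the erythroid list was 0.0766 without AVP_042_4, 0.174 without AVP_043_4, 0.0622 without AVP_974_4, 0.0564 without Sal_046_5 and 0.395 without Sal_975_2. That of the renin-angiotensin list was 0.0913 without AVP_042_4, 0.141 without AVP_043_4, 0.0590 without Sal_043_5, 0.0554 without Sal_046_5 and 0.0845 without Sal_975_2. The erythroid call also ended under each other scaling (0.0759 with median-ratio scaling, 0.0821 after quantile normalization and 0.0630 when rescaled), without a filter (0.0910), with the filter of 5 TPM (0.166), with library weights (0.163), and with the Y-linked (0.251) or yolk sac (0.151) covariate. The renin-angiotensin call also ended without a filter (0.0910), with the filter of 5 TPM (0.166), after quantile normalization (0.0557), with the Y-linked (0.0643) or yolk sac (0.199) covariate and without the 5 libraries with high Afp (0.0964).

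**Figure D5:**
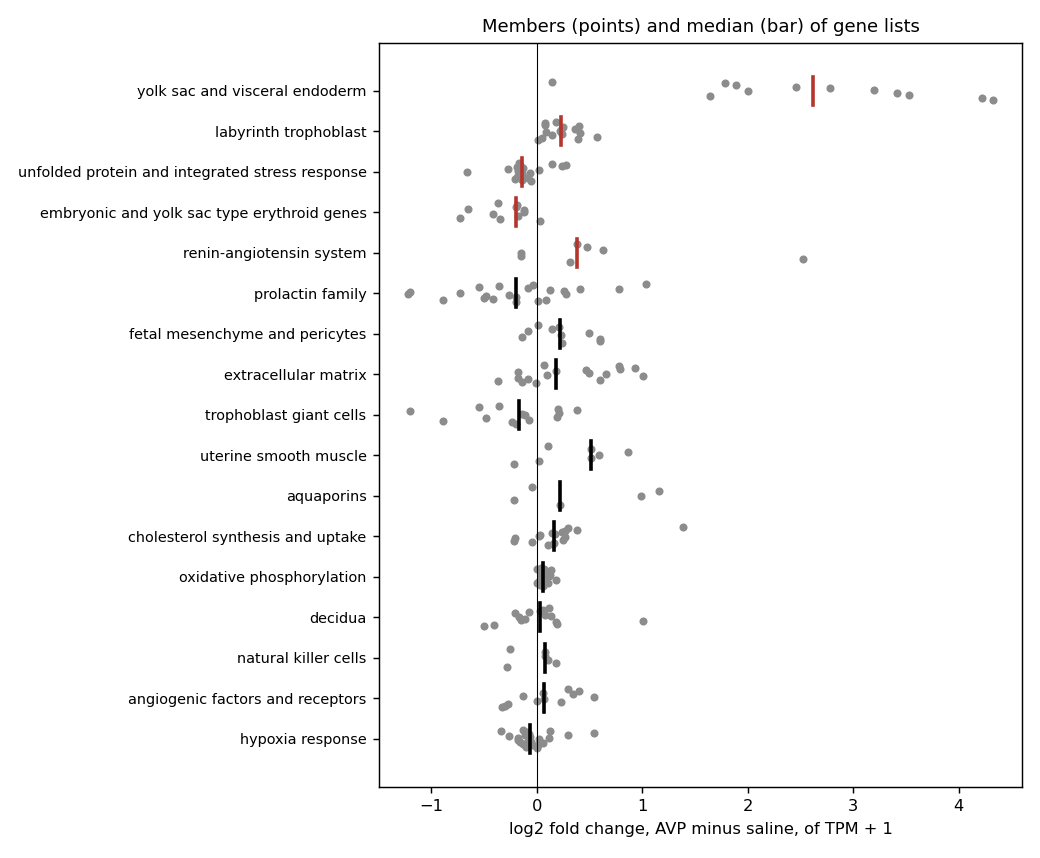
Log2 fold change of TPM + 1, AVP minus saline, of each measured member (grey points) and the median (bar) of 17 of the 40 lists tested, with the bar in red for the 5 lists past camera with a preset correlation. The yolk sac median is 2.62, and the other 4 red medians lie between -0.19 and 0.38.

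The remaining 35 lists did not pass, although 21 of them passed in at least 1 of the alternatives. With the number series as a covariate 4 of them passed camera: cytosolic ribosomal proteins (lower, adjusted p = 0.000400, range over camera alternatives 1.4e-08 to 0.973), type I interferon response (higher, 0.0131, range 0.000259 to 0.963), cell cycle (lower, 0.0327, range 0.000321 to 0.900) and extracellular matrix (higher, 0.0464, range 0.0127 to 0.838). With that covariate and an estimated correlation none of the 40 lists passed, with adjusted p = 0.771 for ribosomal proteins, interferon response and extracellular matrix and 0.789 for cell cycle. Of the 532 different list members measured, none passed over all genes and 24 had an unadjusted p under 0.05 in limma, against 631 of all 13293 genes tested. Adjusting over a list alone takes no account of the 40 lists tested. By that measure the count of members past the threshold was 0 in each list except aquaporins, where it was 1. That gene was Aqp8, a water channel of the placenta, at 23.3 ± 8.59 TPM in AVP and 11.4 ± 5.08 TPM in saline (SD, n = 6 and 4, limma adjusted p = 0.0281 over the list alone and 0.867 over all genes). Its value over the list alone was 0.0571 without AVP_042_4, 0.0528 without AVP_043_4, 0.109 without Sal_043_5, 0.0956 without Sal_046_5 and 0.0634 without Sal_975_2. It was 0.0523 without a filter, 0.0653 with the Y-linked covariate, 0.106 with the yolk sac covariate and 0.884 within the 97 libraries alone, in a range of 0.00167 to 0.884 over all alternatives. Aqp11 was at 3.12 ± 2.16 TPM in AVP and, in saline, at 4.03 TPM in Sal_975_5 and at most 0.292 TPM in the others. Of the 5 aquaporins measured, 3 averaged higher (camera adjusted p = 0.132).

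The structural and stromal lists did not pass the test in the fit reported, and decidual genes were divided. In the other lists most members averaged higher in AVP. Of 10 fetal mesenchyme and pericyte genes 8 did (camera adjusted p = 0.0871), with Col3a1, a fibrillar collagen gene, at 123.9 ± 51.2 and 77.3 ± 13.6 TPM and Dlk1, an imprinted Notch ligand gene, at 87.2 ± 28.9 and 57.6 ± 22.3 TPM. Of 17 extracellular matrix genes 11 did (adjusted p = 0.0871), with Timp3, a metalloproteinase inhibitor, at 12.4 ± 2.68 and 8.70 ± 1.86 TPM and Col6a1 at 6.82 ± 3.37 and 3.06 ± 1.75 TPM. Of 7 uterine smooth muscle genes 6 did (adjusted p = 0.127), with Acta2 at 58.7 ± 16.2 and 40.9 ± 14.0 TPM and Tagln at 38.2 ± 19.1 and 24.2 ± 8.997 TPM. Of 15 decidual genes 8 averaged higher and 7 lower (adjusted p = 0.795), with Lum, the lumican gene, at 46.5 ± 29.7 and 19.2 ± 8.08 TPM and Alpl, an alkaline phosphatase gene, at 123.5 ± 26.2 and 109.2 ± 23.9 TPM. After quantile normalization 7 averaged higher and 8 lower.

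Among immune cells, 6 of 10 macrophage genes averaged higher (camera adjusted p = 0.272), with Lyve1 at 6.26 ± 0.492 and 4.91 ± 1.598 TPM and Mrc1, the mannose receptor gene, at 1.78 ± 0.657 and 1.20 ± 0.505 TPM. Of 6 natural killer cell genes 4 averaged higher, although the test pointed to lower values (adjusted p = 0.615), and after quantile normalization 3 averaged higher and 3 lower. Il2rb, an interleukin receptor gene of these cells, was at 33.9 ± 10.7 and 40.9 ± 12.0 TPM, and the chemokine gene Ccl5 at 0 to 3.32 TPM in AVP and 0.445 to 1.502 TPM in saline. Neutrophil genes averaged lower for 3 of 4 (adjusted p = 0.630), and T and B lymphocyte genes higher for 2 of 3 (adjusted p = 0.630, none higher after quantile normalization). Type I interferon response genes averaged higher for 13 of 17 (10 after quantile normalization, adjusted p = 0.195), interferon gamma and antigen presentation genes for 9 of 17 (adjusted p = 0.582, 8 of 17 under each other scaling), chemokines for 7 of 12 (adjusted p = 0.949, with a mean of -0.04 and a median of 0.07) and complement and coagulation genes for 14 of 23 (adjusted p = 0.424).

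Vascular and hormone pathways were mixed. Of 16 nitric oxide, endothelin and prostaglandin genes 9 averaged higher (camera adjusted p = 0.949) and 6 did after quantile normalization. Ednrb, an endothelin receptor gene, was at 6.15 ± 2.65 and 10.54 ± 3.66 TPM and Ramp2, the adrenomedullin receptor partner, at 63.2 ± 14.9 and 49.6 ± 15.6 TPM. Of 13 steroid hormone genes 7 averaged lower (adjusted p = 0.234), among them Star, which delivers cholesterol for steroid synthesis, at 17.8 ± 3.59 and 27.4 ± 8.72 TPM and Cyp17a1, the steroid 17-hydroxylase gene, at 38.9 ± 10.01 and 52.9 ± 5.77 TPM. Of 24 hypoxia response genes 16 averaged lower (adjusted p = 0.260), with Kdm3a, a histone demethylase induced by hypoxia, at 4.90 ± 1.39 and 6.35 ± 0.864 TPM and Vegfa going the other way. Of 23 oxidative stress response genes 17 averaged higher (14 when rescaled, adjusted p = 0.195), with the extracellular superoxide dismutase Sod3 at 17.3 ± 6.88 and 8.61 ± 5.18 TPM and catalase, Cat, at 53.1 ± 10.2 and 41.0 ± 7.34 TPM. Of 10 osmotic stress response genes 7 averaged lower (adjusted p = 0.352), with the amino acid transporter Slc38a2 at 64.8 ± 4.26 and 72.5 ± 7.09 TPM and Hspa4l at 4.55 ± 1.79 and 5.58 ± 1.22 TPM.

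Metabolic, growth and other remaining lists did not pass the test in the fit reported. All 25 nuclear oxidative phosphorylation genes averaged higher (22 under each of the 3 other scalings), with a median log2 fold change of 0.06 (camera adjusted p = 0.174), and Sdhb was at 158.8 ± 21.3 and 144.7 ± 12.0 TPM and Sdhc at 126.2 ± 5.81 and 120.2 ± 8.56 TPM. Of 17 cholesterol genes 14 averaged higher (adjusted p = 0.166), with Nsdhl, a sterol synthesis enzyme, at 13.2 ± 3.34 and 9.79 ± 2.01 TPM, while the LDL receptor Ldlr was at 70.5 ± 12.6 and 81.0 ± 2.79 TPM. Of 21 nutrient and ion transporters 14 averaged higher (11 when rescaled and 12 with median-ratio scaling, adjusted p = 0.319). The calcium channel Trpv6 was at 3.06 ± 0.630 TPM in AVP and at 0.753 to 0.849 TPM in 3 saline libraries with 3.51 TPM in Sal_975_5, and the fatty acid transporter Slc27a1 was at 6.49 ± 0.903 and 4.77 ± 0.717 TPM. Of 21 imprinted genes 13 averaged higher (11 of 20 when rescaled, adjusted p = 0.335), and the smallest unadjusted p were those of Slc22a18, higher on average, and Sfmbt2, lower on average. Placental cathepsins and their inhibitors averaged lower for 5 of 8 (adjusted p = 0.582, with a mean of 0.06 and a median of -0.15), cell cycle genes for 13 of 21 (adjusted p = 0.465), ribosomal protein genes for 23 of 34 (adjusted p = 0.547), immediate early genes for 13 of 17 (adjusted p = 0.424), heat shock genes for 8 of 9 (adjusted p = 0.214) and Y-linked genes for 3 of 3 (adjusted p = 0.270).

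All gene tests above were two-sided limma tests on log2(TPM + 1), a scale that understates the change of genes with low TPM, and the list tests were camera on the same values. Within the 04 libraries alone 201 genes passed, led by yolk sac genes, and within the 97 libraries alone none did (178 at an unadjusted p under 0.05). The difference in AVP effect between these sets of libraries was itself tested, and 0 genes passed the limma interaction test (433 at an unadjusted p under 0.05).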

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

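The test of Sal_975_5 against the other saline libraries, the test of the overlap of the groups and the fits without libraries with high Afp were chosen after the values had been seen. Of 173 sets of values screened, 16 held a library far from the others of its group, against 8.7 at 1 in 20. That figure takes the sets as independent, which they were not: 7 of the 16 were in Sal_975_5, several of them yolk sac genes.

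In Sal_975_5 the yolk sac genes stood far above the other saline libraries. Afp was at 5966 TPM there and at most 38.1 TPM in the others, Apoa1 at 1783 TPM, Ttr at 717 TPM, Apoc2 at 115.5 TPM and Agt at 25.1 TPM. Among the saline libraries Aqp11, at 4.03 TPM, and Trpv6, at 3.51 TPM, were also highest in this library by far. Among the AVP libraries, AVP_974_4 was far above the rest for Syna (147.4 TPM against 82.5 to 89.2), Gjb2 (813.6 TPM), Aqp8 (39.8 TPM) and Retn (9.15 TPM), of which Syna and Gjb2 are labyrinth markers. AVP_974_5 was highest by far for Tagln (74.2 TPM) and Ccl5 (3.32 TPM), AVP_974_2 for Slc4a1 (25.9 TPM), and AVP_043_4 for Dna2 (24.2 TPM) and for the accession-named transcript (2.11 TPM).

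For the higher average of yolk sac and visceral endoderm genes in AVP, a rise in every AVP placenta could not be decided: for 11 of the 12 measured members the lowest AVP library, AVP_974_5 in most cases, lay below the highest saline library other than Sal_975_5, but for only 3 did the next lowest AVP library too. Yolk sac tissue carried along with some placentas of either group is a candidate explanation that also stays open, since the 11 of 12 members at least 5 times higher in Sal_975_5 than in each other saline library are the values that raised it. Without the 5 libraries with high Afp (2 AVP against 3 saline) the list had a camera adjusted p of 0.0274 with the preset correlation. It was 0.6248 with an estimated correlation, in a range of 7.1e-18 to 0.994 over camera alternatives. The upper end came with the yolk sac marker mean as a covariate, made from the list's own members, so that loss was fixed in advance. Among the libraries left, Afp was at 203 TPM in AVP_974_4 and at 18.5 TPM in AVP_974_5, the latter inside the range of the 3 saline libraries. Chance cannot be excluded for the number of lists called, since 94 of 100 splits of the libraries into 6 and 4 gave at least the 5 lists of AVP and saline, with 25 in the highest of the others. An effect of AVP on the share of such tissue was not tested and stays open.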

How the results depend on the processing

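The fits by number series, by shared number and by yolk sac markers, and those without libraries with high Afp or without small RNAs, were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. The mitochondrial share was not run for lack of named genes, and the robust variance and the random block apply to genes only, since camera takes neither.

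The count of 1 gene changed, 0 higher and 1 lower held under each alternative set in advance except the filter of 5 TPM (0 changed, 0 lower), whose construction removes Mir669h, and the fit without Sal_046_5, where Mir677 also passed. Leaving out 1 library gave 1 to 2 genes changed and 0 to 1 higher. Of the added fits, the 97 libraries alone gave 0 changed and 0 lower, the 04 libraries alone 201 changed (181 higher and 20 lower), the fit without the 5 libraries with Afp of at least 1000 TPM 0 changed and 0 lower, and the fit without small RNAs and accession names 0 changed and 0 lower, the last by construction. The first 3 hold fewer samples, and otherwise the cause was not tested.

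Against 5 lists moved, there were 3 without a filter, 3 with the filter of 5 TPM, 3 after quantile normalization, 8 with library weights, 8 with the Y-linked covariate, 9 at a threshold of 0.10, 0 with an estimated correlation, 0 with fry, 9 with the number series as a covariate, 0 in the 97 libraries, 14 in the 04 libraries and 14 without the high-Afp libraries, and 0 in each of the series-covariate and high-Afp fits with an estimated correlation. Leaving out 1 library gave 4 to 12, with 12 without AVP_976_4, 9 without Sal_975_5 and 8 without AVP_042_4. The cause was not tested, apart from correlation between members, which the estimated correlation and fry take in. Over 32 alternatives, fry included, the yolk sac list stayed past the threshold in 26, labyrinth trophoblast in 27, unfolded protein response in 19, renin-angiotensin in 16 and erythroid genes in 14, and none changed direction. Camera adjusted p values ran from 7.1e-18 to 0.994 for yolk sac, 1.7e-05 to 0.838 for labyrinth, 9.6e-05 to 0.838 for unfolded protein response, 9.9e-05 to 0.838 for erythroid and 0.00248 to 0.838 for renin-angiotensin genes. The 0.994 for yolk sac came with the yolk sac marker mean as a covariate, made from the members of that list. Its loss of the call there, counted in the 32 alternatives, was fixed in advance. The threshold of 0.10, also counted, was applied to the fit reported, so the 5 lists keeping their call there was fixed in advance too.

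Of 83 named genes, 77 kept the sign of their log2 fold change in each of the 29 alternatives run on genes. Eng, at 0.00 in the fit reported, was at -0.0001 with a pseudocount of 0.1, -0.0129 with median-ratio scaling, -0.006 with quantile normalization, -0.0207 when rescaled, -0.0085 with library weights, -0.0859 with the Y-linked covariate and -0.22 in the 97 libraries, and -0.0534 to 0.1217 leaving out 1 library (lowest without AVP_043_4). Tpbpa was at 0.10 after quantile normalization and -0.1867 to 0.0471 leaving out 1 library. In the 04 libraries Lnpep was at 0.17, Sdhb at -0.0171 and Hspa4l at 0.0688. Ccl5 was at 0.16 with the yolk sac covariate and 0.0443 without the high-Afp libraries. None of these genes passed the threshold, and the cause was not tested. Depth is unknown, so no limit from it can be given. The makeup of the libraries gave 0 of 4 differences in both versions.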

Other observations

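The test of the number series by splits was chosen after the result had been seen. With AVP in the model, 1745 of 13293 genes differed between the 4 libraries whose column numbers begin with 04 and the 6 that begin with 97 (limma, adjusted p under 0.05), 660 higher and 1085 lower in the 04 libraries. Csf1r, the receptor gene for macrophage colony-stimulating factor, was at 221.9 ± 18.3 TPM in the 04 libraries and 108.8 ± 12.5 TPM in the 97 libraries (SD, n = 4 and 6, limma adjusted p = 0.01004). Serpine1, plasminogen activator inhibitor 1, was at 598.2 ± 56.7 and 225.2 ± 47.0 TPM, and Tfpi, tissue factor pathway inhibitor, at 844.1 ± 280.5 and 317.3 ± 72.9 TPM. Of 34 ribosomal protein genes tested 30 passed as lower in the 04 libraries, as did 17 of 25 nuclear oxidative phosphorylation genes and 10 of 21 cell cycle genes. Past the threshold as higher were 6 of 22 pregnancy-specific glycoprotein genes and 7 of 22 prolactin family genes. Members of a list vary together, and each of these lists had a camera adjusted p of 0.478 with an estimated correlation. Of 15 decidual genes 0 passed limma's threshold between the series (4 at an unadjusted p under 0.05), and 13 averaged higher in the 04 libraries, with a median log2 difference of 0.85 (camera adjusted p = 0.0230, adjusted p = 0.579 with an estimated correlation). Of 4 neutrophil genes 1 passed, and all 4 averaged higher, with a median of 0.69 (camera adjusted p = 0.0386, adjusted p = 0.478 with an estimated correlation). The genes named here were chosen after their values were seen.

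For the number series, transcript length was taken as the median over each gene's annotated transcripts, which need not be the length of the deposited one. On that measure length is argued against as the whole cause of the number of genes called. The genes lower in the 04 libraries had a median transcript length of 816.5 nucleotides and those higher 2039.5, but 1596 genes passed after each library's trend with length was taken out, against 1737 before. These are totals of separate fits. Whether the same genes passed in both, and in the same direction, was not checked, so length stays open as a part of the cause. A difference in the share of decidua and yolk sac could not be decided: with both marker means as covariates the median gene kept 0.774 of its log2 difference, 0.683 to 0.826 leaving out 1 library, and 0 genes passed with 5 parameters fitted to 10 libraries. Splits of the libraries could not exclude chance as the origin of this count, since the series was taken up after the data were seen. Of 100 splits drawn from the 210 possible, the series itself included by choice, only the series gave its 1976 genes without AVP in the model. The highest other split gave 1256. That other split holds AVP_974_2, AVP_974_4, AVP_976_4 and Sal_975_5, which were low in the killer cell gene Gzmd, at 50.2 to 347.8 TPM. Sal_043_5, outside the split, was nearly as low at 412.5 TPM. A structure of the samples by tissue was not tested for this split. The labels do not say what the numbers stand for, so batch, litter and stage stay open as explanations, and beyond the share of decidua and yolk sac no biological one was tested.

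Mir669h was listed at 0 in all AVP libraries. Lower transcription of its host Sfmbt2 could not be decided as the cause. The 95% interval of the Sfmbt2 log2 fold change, -0.66 to 0.01, excludes a fall of 1 but allows a smaller one. Sfmbt2 was also read from 1 transcript, and Mir669h lies in an intron. Reads assigned to other microRNA entries inside Sfmbt2 could not be decided: the sum of 42 such entries was lower in AVP by 1.54 TPM (a difference of -1.54, exact permutation p = 0.700), with most entries at 0. Chance cannot be excluded for a count of 1 gene, since 23 of 100 splits gave at least 1 gene, with 1976 in the highest of the others, the number series. Entries at 0 in all libraries of a group and at 1 TPM or more in all of the other occurred in 57 of the 210 possible splits, so a candidate explanation is sampling of a short, rarely read transcript.

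In Sal_975_5, Eif2s3y at 6.49 TPM stood beside Xist at 24.2 TPM, and in Sal_046_5 and Sal_975_2, with Eif2s3y at 20.2 and 25.9 TPM, Xist was at 5.38 and 4.56 TPM, against 0.482 and 0.734 TPM in AVP_974_2 and AVP_976_4.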
